A study of Homo sapiens with 59 samples.

How the data were processed

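H3K27ac ChIP-seq peak lists of 20 tumours and an RNA-seq count table of 19 tumours were analysed. Per the labels' protocols, flash-frozen cores from epithelium-rich parts of each tumour were pulverised and fixed with formaldehyde, chromatin was precipitated with an H3K27ac antibody, and RNA came from a separate core. Tumours were put into the 4 histotypes by their labels, and numbers from the labels name tumours. Tumours were treated as separate samples, and p-values measure the spread between them, apart from Fisher's test of genes shared between lists, which takes genes as samples.

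The RNA values are raw counts per gene as the authors deposited them, with gene models on GRCh38. Per the submitters' processing notes, STAR 2.5.1b and featureCounts 1.5.0-p1 were among the tools, and GRCh38.p10, hg38 and hg19 among the builds. The gene lengths that came with the table, the other kind of value the authors deposited there, were not used. Whether counting used strand is not given in the sources used here, so antisense and overlapping genes are uncertain. In the peak lists, the authors deposited a score, a fold enrichment ratio, and −log10 p and −log10 q values for each peak of each tumour, called per tumour. Per the file headers and layout no caller is named, and the peak caller is not given in the sources used here. The position of each peak's summit is a value of another kind that the authors deposited and was not used. Peak ends fit GRCh37 chromosome lengths and exceed those of GRCh38, so peaks were read on GRCh37. The 2 data types were joined only by gene identifier, and no coordinate was converted between builds.

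Of 60554 genes in the count table, 56958 (94.1%) had a symbol, and 516 of 521 entries of the gene lists were matched. No 2 libraries held identical values (0 pairs). Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr and a quasi-likelihood F test in 1 fit of all 19 tumours. Each contrast was a histotype minus the mean of the other 3, two-sided, with Benjamini-Hochberg adjustment over 29170 genes and a threshold of 0.05. A gene high in 1 histotype thus pulls down the contrasts of the other 3. All gene-level adjusted p-values come from this test unless another tool is named. The SE was the size of the log2 fold change divided by the square root of F. TMM factors ran from 0.658 to 1.477, apart from 0.293 in MOC 2. Levels are log2 CPM with a prior count of 2. With no scaling beyond library size, the median log2 fold change of all genes moved to −0.116 in CCOC and 0.214 in EnOC.

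Gene lists, 30 in all, were tested with limma 3.58.1's camera with a preset correlation of 0.01, adjusted over the 30 lists of a histotype. Camera calls were 15 lists in CCOC (6 up, 9 down), 14 in EnOC (5 and 9), 12 in HGSOC (6 and 6) and 5 in MOC (3 and 2). In CCOC the estimated correlations ran from −0.094 for mismatch repair genes to 0.965 for mitochondrially encoded genes. Where the correlation is above 0.01, the preset gives p-values that are too small. With an estimated correlation 1, 0, 0 and 1 lists held, the clear cell markers in CCOC and the gastrointestinal mucinous genes in MOC, and with fry 3, 1, 3 and 1. A list's median, mean and test were not all of the same sign for 3 lists in CCOC, 3 in EnOC, 4 in HGSOC and 5 in MOC, none of which passed. Among them were glucose and glycogen genes in CCOC (median 0.392, mean −0.276, test down), immediate early genes in CCOC and EnOC, oxidative stress genes in EnOC, adipocyte genes in EnOC and HGSOC, and estrogen response, Wnt target and endothelial genes in HGSOC. Genes were named by a rule: for each contrast the 10 largest and 6 smallest log2 fold changes among called genes with all own tumours on the same side of the median of the others, the 3 members with the smallest p of each list that passed, and 20 fixed markers. DESeq2 1.42.0 and limma-voom served as alternatives. DESeq2 gave no adjusted p for 493, 5002, 2751 and 3313 genes in CCOC, EnOC, HGSOC and MOC.

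Peaks of all tumours were merged into regions (1546881 of 1546918 peaks used), and a tumour had a region if any of its peaks overlapped it. Presence in 5 own against 15 other tumours was tested with Fisher's exact test for regions in 4 to 16 tumours. As no region passed, the sets used for nearby genes were those of the planned call without a test, in at least 4 own and at most 1 other tumour. A region was assigned to the protein-coding gene with the nearest start, within 50 kb. Promoters were 1 kb either side of a start, from 19747 protein-coding genes on GRCh37. Similarity within against between histotypes used the Jaccard index for regions and Spearman's correlation for log2 CPM, with 100000 permutations of the histotype labels, one-sided. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.

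Library totals ran from 7416560 counts in EnOC 5 to 36110946 in EnOC 4, which bounds the precision for low genes. Intervals cover counting error only. The steps were tested on simulated data. With 200 changed genes among 29170, edgeR recovered 59% of 4-fold and 95% of 16-fold changes in CCOC, 50% and 93% in EnOC, 49% and 92% in HGSOC and 43% and 95% in MOC, with 5, 3, 6 and 8 false calls. The region test recovered 100% of 200 planted regions among 60000 and 0% of 20, with 0 false calls, so it can make calls only where many regions share the pattern.

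Tests, samples, named-gene rule and most alternatives were chosen before the data were examined. The alternatives covered scaling, filters, tool, contrast, replicate number as a block, set test, peak threshold, overlap, bins, distance and each tumour left out in turn. Leaving out the 3 mitochondrial-rich libraries, or 5 doubted libraries (CCOC 1, CCOC 5, EnOC 5, HGSOC 4 and MOC 2), was added after seeing the data, and the second set was chosen partly from the RNA levels themselves. Also added then were the regions depleted in a histotype, the comparison of promoter shares of gene lists and the use of region centres for promoters. Genes that identify a person's sex were left out of every step. Some named genes are not reported here.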

Results

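Primary tumours of 4 histotypes of epithelial ovarian cancer were profiled to compare their active regulatory regions and their transcripts. The histotypes were clear cell (CCOC), endometrioid (EnOC), high-grade serous (HGSOC) and mucinous (MOC) carcinoma, which differ under the microscope and in the normal tissues they resemble. Acetylation of lysine 27 of histone H3 (H3K27ac), which is found on chromatin of promoters and enhancers in use, was mapped by ChIP-seq in 20 tumours, 5 of each histotype. RNA-seq counts were used from 19 of these tumour labels, 5 for CCOC, HGSOC and MOC and 4 for EnOC. Each tumour was a separate sample, named here by histotype and number.

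The RNA libraries held between 7416560 and 36110946 counts. The 2 mitochondrial ribosomal RNA genes took 39.8% of the counts in CCOC 5, 40.7% in EnOC 5 and 42.8% in MOC 2, against 5.52% to 25.8% in the other libraries. Several tumours stood apart from their histotype in marker genes. EPCAM, an adhesion protein of epithelial cells, was at −0.02 log2 CPM (counts scaled by the size of the library) in HGSOC 4 and at 7.58 to 8.14 in the other HGSOC tumours. PAX8, a transcription factor of the Müllerian epithelium, was at 1.77 log2 CPM in CCOC 1 and at 8.95 to 11.12 in the other CCOC tumours. In MOC 2, PAX8 was at 7.34 log2 CPM, against 2.55 to 3.59 in the other MOC tumours. A comparison of each RNA library with all peak lists over 2696 promoters matched 14 libraries best with the list of the same histotype and number, 4 with another list of their histotype and 1 with a list of another histotype.

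The first question was how the H3K27ac landscape was shared among tumours. The peak lists held 91061 ± 22148 peaks in CCOC, 78153 ± 25132 in EnOC, 65092 ± 11536 in HGSOC and 75070 ± 20326 in MOC (mean ± SD, n = 5 each). These differences were within the spread between tumours (CCOC minus the others 18289.8 peaks, two-sided exact permutation p = 0.084, adjusted over the 4 histotypes 0.264; HGSOC −16336.1, exact p = 0.132). Merging all peaks gave 295233 regions covering 351.9 Mb of the genome, of which 12954 were marked in all 20 tumours and 150407 (50.9%) in a single tumour. Promoters, taken as 1 kb either side of the start of a protein-coding gene, overlapped 79.3% of the regions shared by all tumours and 4.08% of the other regions (odds ratio 90.03). The shared regions were wider, with a median of 3935.5 bp against 565 bp, and wide regions reach more promoters by construction. With the centre of each region in place of its whole width, the shares were 61.56% and 3.14% (odds ratio 49.34). Of regions in a single tumour, 1.99% overlapped a promoter.

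**Figure D1:**
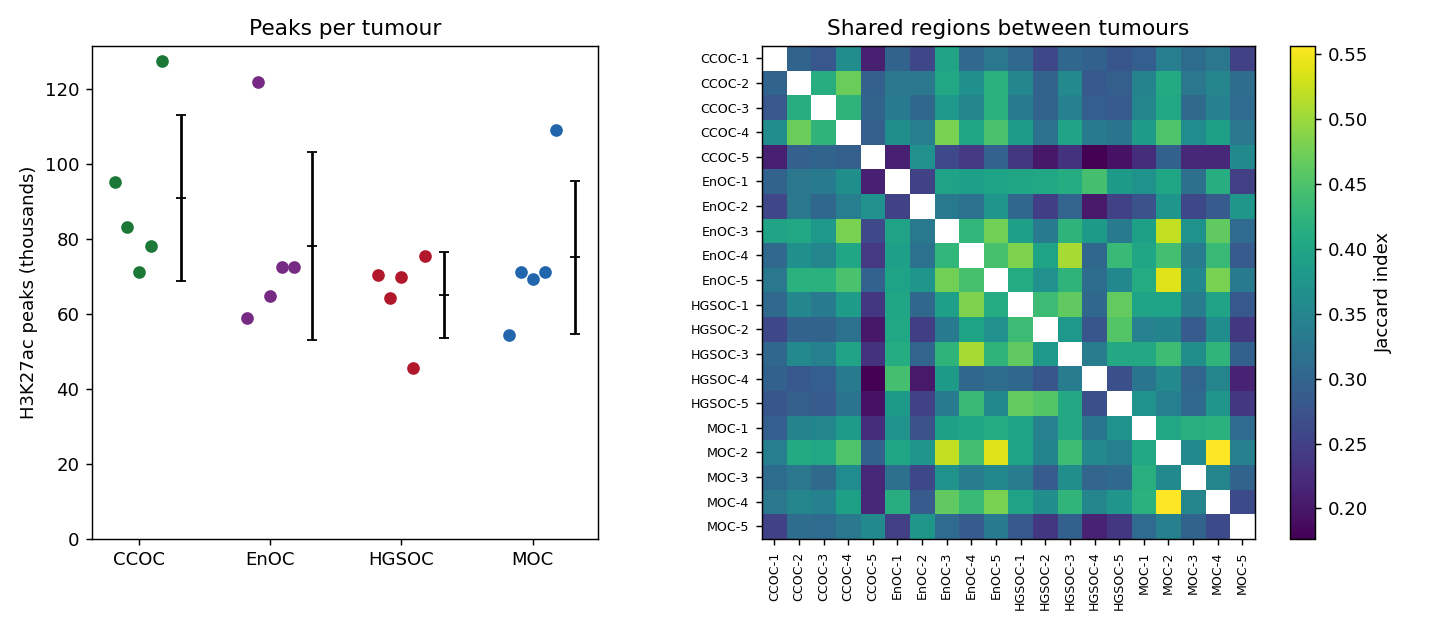
H3K27ac peak lists of the 20 tumours. One panel gives the number of peaks per tumour (points) with mean ± SD per histotype (n = 5 each), and the other the Jaccard index of each pair of tumours over the 295233 regions, from low to high on the colour scale. CCOC had 91061 ± 22148 peaks, and pairs of 1 histotype shared a mean index of 0.366 against 0.342 between histotypes.

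On average, tumours of 1 histotype shared slightly more regions than tumours of different histotypes. The mean Jaccard index was 0.366 within and 0.342 between histotypes, a difference of 0.0243 (one-sided permutation p = 0.0057). The mean index was lowest between CCOC and HGSOC tumours, at 0.295, and between EnOC and MOC tumours it was 0.376, against 0.38 among EnOC tumours themselves. Among CCOC tumours it was 0.334, below the 0.345 between CCOC and EnOC tumours. The most similar tumour was of the same histotype for 2 of 5 CCOC, 0 of 5 EnOC, 2 of 5 HGSOC and 4 of 5 MOC tumours. In RNA, the mean Spearman correlation across genes was 0.842 within and 0.821 between histotypes, a difference of 0.021 (one-sided permutation p = 0.00012). The nearest tumour in RNA was of the same histotype for 4 of 5 CCOC, 0 of 4 EnOC, 1 of 5 HGSOC and 3 of 5 MOC tumours.

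H3K27ac regions were then compared between each histotype and the other 15 tumours. Regions restricted to a histotype, in at least 4 of its tumours and at most 1 other, numbered 663 in CCOC, 357 in HGSOC, 146 in MOC and 32 in EnOC. On GRCh37, CCOC-restricted regions included chromosome 22, 17709418 to 17713762, which overlaps an exon and the promoter of ADA2, and chromosome 8, 8927378 to 8928722, in an intron of ERI1. HGSOC-restricted regions included chromosome 14, 71821412 to 71823578, in an intron of SIPA1L1. MOC-restricted regions included chromosome 8, 110596538 to 110603659, over an exon of SYBU, and chromosome 9, 71353172 to 71357446, over an exon of PIP5K1B. These 5 regions were marked in 5 of 5 own tumours and 0 of 15 others (Fisher's exact p = 6.45e-05). EnOC-restricted regions included chromosome X, 110207683 to 110208862, in an intron of PAK3, marked in 4 of 5 EnOC tumours and 0 of 15 others (Fisher's exact p = 0.00103, adjusted p = 1). Promoters overlapped 4.22% of the CCOC-restricted regions (exact 95% interval 2.82 to 6.05), 1.96% of those of HGSOC (0.79 to 4), 5.48% of those of MOC (2.4 to 10.51) and 0 of 32 of those of EnOC (0 to 10.89).

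No single region passed the adjusted test. Fisher's exact test with Benjamini-Hochberg adjustment over 56957 regions called 0 in every histotype, with smallest adjusted p of 0.16, 1, 0.362 and 0.367 in CCOC, EnOC, HGSOC and MOC. At an unadjusted p under 0.05, 3407 regions were gained and 986 lost in CCOC, 824 and 48 in EnOC, 2427 and 2315 in HGSOC, and 1388 and 520 in MOC. Other splits of the tumours into groups of the same sizes, chosen after the result was seen, gave a median of 979 such regions. Of 100 splits, the histotypes included, 3 gave as many as CCOC, 59 as EnOC, 2 as HGSOC and 17 as MOC. No other tool was run on the peaks. The design limits this test, since 74 regions in all 5 own and no other tumour would have been needed for a call and 23 existed in CCOC, 0 in EnOC, 5 in HGSOC and 10 in MOC. The restricted counts, which rest on a rule and no test, fell as low as 110 without CCOC 2 or CCOC 3, 122 without CCOC 4 and 137 without CCOC 5. Those of HGSOC were 12, 17, 26 and 10 without HGSOC 1, 2, 3 and 5, and 547 and 623 without EnOC 1 and EnOC 4. Those of MOC were 43, 54, 59, 51 and 55 without MOC 1 to MOC 5, and those of EnOC 20, 1, 8, 4 and 3 without EnOC 1 to EnOC 5, 54 without HGSOC 3 and 59 without MOC 2. With 1 own tumour left out, the rule asks for all 4 that remain. The counts also moved with the definition of a region. With the same number of strongest peaks from each tumour they were 302 in CCOC, 33 in EnOC, 277 in HGSOC and 167 in MOC, and with at least 50% of a region covered they were 349, 61, 299 and 97. They were 466, 57, 204 and 146 with −log10 q of at least 5, and 1393, 86, 1162 and 483 in bins of 1 kb.

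Promoters of marker genes showed the same mark in different numbers of tumours. The promoter of HNF4A, a transcription factor of liver and gut, starts at chromosome 20, position 42984339 (GRCh37), and was marked in 5 of 5 CCOC, 2 of 5 EnOC, 0 of 5 HGSOC and 3 of 5 MOC tumours, and that of TFF3 in 1, 3, 3 and 5. PAX8, WT1, ANXA4, ARID1A, CCNE1, CDKN2A, MKI67 and KRT7 had marked promoters in all 20 tumours. Across the 29 gene lists with nuclear promoters, no list differed in its share of marked promoters after adjustment. Gastrointestinal mucinous genes had 60.7% ± 23.7 of promoters marked in MOC and 29.3% ± 17.3 in the others (SD, n = 5 and 15). After subtraction of each tumour's share over all promoters the difference was 30.66 points (exact permutation p = 0.00297, adjusted p = 0.086, and 0.0534 over the 18 lists with 10% to 90% marked). HOX genes, which pattern the body axis, had 44.2% ± 5.5 marked in HGSOC and 77.2% ± 20.9 in the others, a corrected difference of −27.25 points (exact permutation p = 0.00697, adjusted p = 0.0505, and 0.101 over the 18 lists). In CCOC they had 91.5% ± 5.8 marked, against 61.4% ± 22 in the others, a corrected difference of 26.58 points (exact permutation p = 0.01032, adjusted p = 0.1496, and 0.0929 over the 18 lists). Endothelial genes had 84.6% ± 7.7 marked in CCOC and 54.9% ± 20.3 in the others. Their corrected difference was 26.23 points (exact permutation p = 0.00709, adjusted p = 0.1496, and 0.0929 over the 18 lists). In HGSOC 4, 55% of epithelial promoters were marked, against 95% to 100% in the other tumours.

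In RNA, clear cell carcinoma differed from the mean of the other histotypes in a programme of clear cell marker genes. EEF1A2 (ENSG00000101210), a translation elongation factor normally limited to nerve and muscle, was higher by 8.44 ± 0.89 (log2 fold change ± SE; adjusted p = 0.000232), at 6.82 ± 1.67 log2 CPM in CCOC and −1.42 ± 2.25 in the others (SD, n = 5 and 14). LAMB1, a laminin chain of basement membrane, was higher by 3.01 ± 0.4 (adjusted p = 0.00108), at 9.33 ± 0.49 and 6.19 ± 1.15 log2 CPM. TFF3, a secreted trefoil peptide of mucous epithelia, was lower at −6.87 ± 1.4 (adjusted p = 0.0106). In CCOC it was at −3.7 to −1.38 log2 CPM. The other histotypes were at −1.54 to 3.61 (EnOC), −0.19 to 2.2 (HGSOC) and 5.31 to 10.71 (MOC).

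Of the 17 measured clear cell markers, 12 rose in CCOC and 5 did not pass, and 14 rose when adjusted over the list alone. Their median log2 fold change was 3.474 (camera adjusted p = 7.64e-22, and 0.00922 with an estimated correlation). The mean level of these markers was 3.85 log2 CPM in CCOC 1 and 5.78 to 7.94 in the other CCOC tumours. It was 5.08 in EnOC 2 and 4.63 in MOC 5, so CCOC 1 did not share this programme. FXYD2, a subunit that regulates the sodium pump, was higher by 6.83 ± 0.94, GLRX, a redox enzyme, by 3.67 ± 0.55 and ANXA4, an annexin, by 2.87 ± 0.52 (adjusted p = 0.00125, 0.00173 and 0.00568). In CCOC 1, FXYD2 was at 1.23 log2 CPM, against 5.65 to 9.36 in the other CCOC tumours. NAPSA, an aspartic protease used to diagnose this histotype, was at 2.52 ± 0.71 and did not pass (adjusted p = 0.056), with −2.69 log2 CPM in CCOC 1. DPPA2, a gene of early embryonic cells, was higher by 8.17 ± 1.32, and F2, prothrombin, by 7.54 ± 1.1 (adjusted p = 0.00444 and 0.00144). F2 was at 7.755 log2 CPM in CCOC 1 and at most 3.152 in the other CCOC tumours, and was higher by 3.59 without CCOC 1 (adjusted p = 0.0191).

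HOX genes had a median of 1.998 in CCOC, with 3 of 33 higher, and 7 when adjusted over the list alone (camera adjusted p = 4.74e-09). With an estimated correlation the adjusted p was 0.129. HOXD10 was higher by 4.76 ± 0.88 (adjusted p = 0.00637), and 2.99 without CCOC 3 (adjusted p = 0.085). Serous markers had a median of −1.964, with 3 of 20 lower, and 6 lower and 2 higher when adjusted over the list alone (camera adjusted p = 0.00542, adjusted p = 0.72 with an estimated correlation). Among them WT1, a transcription factor of serous tumours and mesothelium, was lower at −3.65 ± 0.94 (adjusted p = 0.0373), and lost the call without CCOC 1, 2, 3 or 4 or EnOC 1, 2 or 4, with an adjusted p of up to 0.11 without CCOC 3. MHC class II genes, which present antigen, had a median of −1.707 with 0 of 11 called, and 6 lower when adjusted over the list alone (camera adjusted p = 7.02e-06, adjusted p = 0.503 with an estimated correlation). Lists of immune cells moved the same way, apart from myeloid genes at 0.73 (camera adjusted p = 0.138). T and NK cell genes had a median of −1.069 with 2 of 21 higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.00522, adjusted p = 0.72 with an estimated correlation), and lost the call without CCOC 2 or CCOC 4 (up to 0.0563). The 2 higher genes each followed 1 tumour, as CCL5 turned to −1.27 without CCOC 3 and CD7 to −1.38 without CCOC 1. B and plasma cell genes had a median of −1.351 with 0 of 13 called, and 0 when adjusted over the list alone (camera adjusted p = 0.0249, adjusted p = 0.72 with an estimated correlation), and lost the call without CCOC 2, CCOC 5 or HGSOC 4 (up to 0.0863). Mesothelial genes had a median of −1.993 with 1 of 11 lower, which was WT1, and 2 when adjusted over the list alone (camera adjusted p = 0.0036, adjusted p = 0.129 with an estimated correlation). Ovarian stromal and steroidogenic genes had a median of −2.336 with 1 of 15 higher, and 1 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.026, adjusted p = 0.722 with an estimated correlation), and lost the call without CCOC 2, 3 or 4, EnOC 2 or HGSOC 4 (up to 0.106). Epithelial genes had a median of 0.492 with 0 of 20 called, and 2 higher when adjusted over the list alone (camera adjusted p = 0.0163, adjusted p = 0.772 with an estimated correlation), and lost the call without CCOC 4 or HGSOC 4 (up to 0.151). Proliferation genes had a median of 0.859 with 0 of 30 called, and 0 when adjusted over the list alone (camera adjusted p = 7.02e-06, adjusted p = 0.72 with an estimated correlation). Without CCOC 1 their median was 0.19 (camera adjusted p = 0.0779).

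In all, 910 of 29170 genes passed in CCOC, 753 higher and 157 lower (edgeR). The count fell to 408 without CCOC 3, and was 2090 by DESeq2 and 355 by limma-voom. AFP, a fetal liver protein, was at 9.06 ± 1.66 (adjusted p = 0.00576) and at −0.83 without CCOC 1 (adjusted p = 0.82). HNF4A was at 4.7 ± 1.08 (adjusted p = 0.0217) and at 1.89 without CCOC 1 (adjusted p = 0.364). UGT1A9, a liver conjugating enzyme that shares exons with its neighbours and so is an uncertain count, was at 8.34, and at 4.27 without CCOC 3 (adjusted p = 0.125). CCNE1, a cyclin of S-phase entry, was higher by 2.47 ± 0.51 (adjusted p = 0.0112), and by 2.09 without CCOC 3 (adjusted p = 0.0594).

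**Figure D2:**
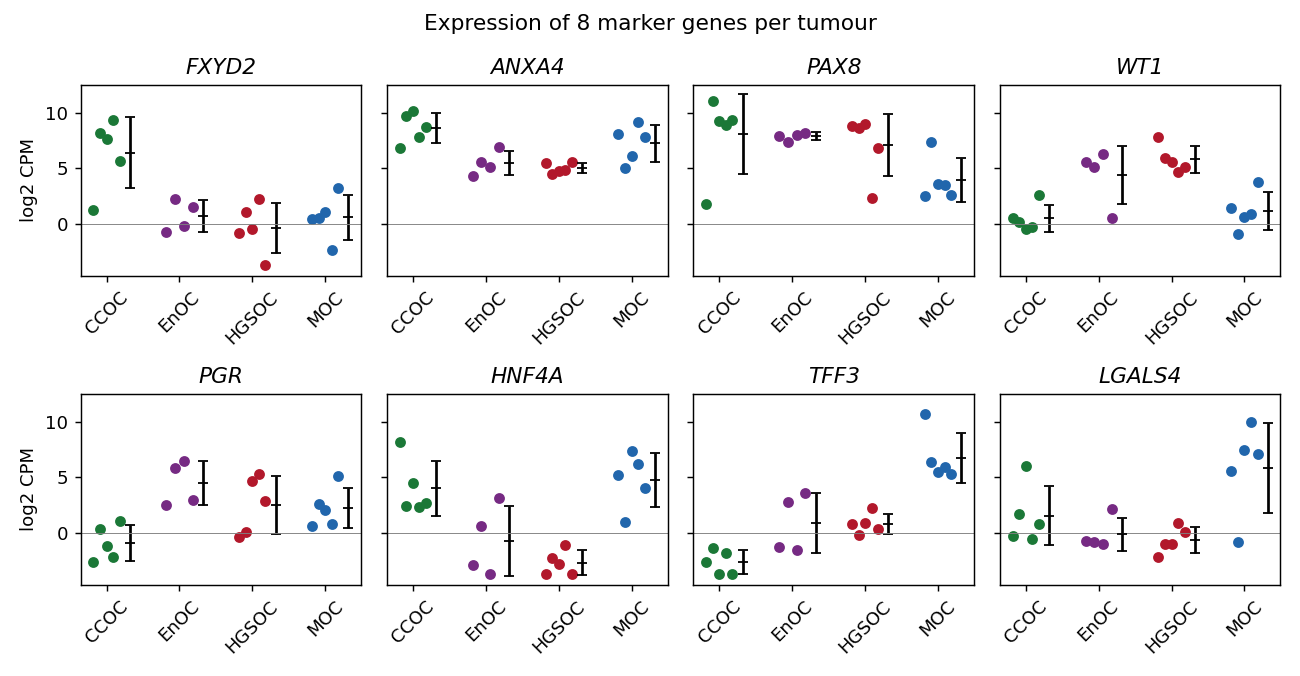
RNA level of 8 marker genes in the 19 tumours, as log2 CPM on the vertical axis, by histotype. Points are tumours and bars give mean ± SD (n = 5 for CCOC, HGSOC and MOC, n = 4 for EnOC). ANXA4 was at 8.68 ± 1.36 in CCOC, WT1 at 5.83 ± 1.23 in HGSOC and TFF3 at 6.75 ± 2.25 in MOC.

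Endometrioid tumours had no gene past the edgeR test against the mean of the other histotypes. The genes with the smallest p, chosen after their values were seen, included DNAH9 (ENSG00000007174), a motor protein of cilia, at 5.04 ± 0.86 (adjusted p = 0.0831), with 2.96 ± 3.97 log2 CPM in EnOC and −0.06 ± 1.48 in the others (SD, n = 4 and 15). GJB6, a gap junction protein, was at 5.95 ± 1.01 and STMN2, a neuronal protein, at 5.49 ± 0.96 (adjusted p = 0.0831 for both). Levels were low and uneven, with GJB6 at 4.78 log2 CPM in EnOC 2 and −0.98 to 1.52 in the other EnOC tumours. STMN2 was at −2.47 in EnOC 2 and 0.56 to 2.88 in the other EnOC tumours. DESeq2 called all 3 of these genes (adjusted p = 0.000992, 0.00954 and 0.035 for DNAH9, GJB6 and STMN2). PGR, the progesterone receptor, was at 3.11 ± 0.86 (adjusted p = 0.288).

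Ciliated cell genes had a median log2 fold change of 2.113 in EnOC with 0 of 15 called by edgeR and 1, DNAH9, by DESeq2, and 8 higher when adjusted over the list alone (camera adjusted p = 2.23e-10). With an estimated correlation the adjusted p was 0.271. Their mean level was 5.57 log2 CPM in EnOC 2 and 4.18 in EnOC 5, against 1.4 in EnOC 1 and 1.45 in EnOC 4. Serous markers had a median of 1.542 with 0 of 20 called, and 3 higher when adjusted over the list alone (camera adjusted p = 2.23e-10, adjusted p = 0.233 with an estimated correlation). Estrogen response genes had a median of 0.422 with 0 of 18 called, and 3 higher when adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.271 with an estimated correlation). They lost the call without EnOC 2 (median −0.041, camera adjusted p = 0.418) or EnOC 4 (0.499, 0.195). B and plasma cell genes had a median of 1.935 with 0 of 13 called, and 1 higher when adjusted over the list alone (camera adjusted p = 0.000237, adjusted p = 0.461 with an estimated correlation), and 0.418 without EnOC 1 (camera adjusted p = 0.481). Clear cell markers had a median of −0.969 with 0 of 17 called, and 0 when adjusted over the list alone (camera adjusted p = 0.00032, adjusted p = 0.271 with an estimated correlation). Their mean level was 2.76 to 5.08 log2 CPM in EnOC, 2.56 to 3.46 in HGSOC and 3.48 to 4.63 in MOC. In CCOC, which is part of the mean of the others, it was 3.85 to 7.94. Endothelial genes had a median of −0.943 with 0 of 13 called, and 0 when adjusted over the list alone (camera adjusted p = 0.00148, adjusted p = 0.505 with an estimated correlation). Mitochondrially encoded genes had a median of −0.974 with 0 of 13 called, and 0 when adjusted over the list alone (camera adjusted p = 0.00351, adjusted p = 0.594 with an estimated correlation), and lost the call without EnOC 2, EnOC 4 or MOC 2 (up to 0.128). Mismatch repair genes had a median of −0.469 with 0 of 8 called, and 0 when adjusted over the list alone (camera adjusted p = 0.00351, adjusted p = 0.113 with an estimated correlation, fry adjusted p = 0.00404), and lost the camera call without EnOC 2 (0.0562).

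The edgeR count of 0 in EnOC stood beside 1819 genes at an unadjusted p under 0.05, 42 genes by DESeq2 and 1 by limma-voom. With no difference at all, a share of about 0.05 of the 29170 genes tested would reach that unadjusted p. Without any filter on low counts 109 genes passed, and with no scaling beyond library size 18 did. Leaving out a single library gave 2 genes without EnOC 1, 6 without EnOC 2, 34 without EnOC 4, 5 without EnOC 5 and 22 without HGSOC 4.

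High-grade serous tumours differed from the mean of the other histotypes in few single genes. CRTAC1 (ENSG00000095713), a secreted cartilage protein, was higher by 6.43 ± 0.9 (adjusted p = 0.0088), at 3.18 ± 2.96 log2 CPM in HGSOC and −1.66 ± 1.27 in the others (SD, n = 5 and 14). It was the only named HGSOC gene of 18 called that held with each of the 19 libraries left out in turn. ANKRD65 was higher by 4.22 ± 0.66 (adjusted p = 0.0175, and 0.0579 without EnOC 2). TOX3, a nuclear protein of the HMG-box family, was lower at −3.79 ± 0.63 (adjusted p = 0.0191, and 0.0619 without HGSOC 5). WT1 was higher by 3.55 ± 0.68 (adjusted p = 0.0419), at 5.83 ± 1.23 and 1.85 ± 2.41 log2 CPM. EnOC 1, 2 and 4 were within the HGSOC range for WT1, at 5.6, 5.13 and 6.28 against 4.68 to 7.86. EnOC 5 was at 0.56, CCOC at −0.5 to 2.58 and MOC at −0.88 to 3.8. For ANKRD65, EnOC 1, 2 and 4 were at 4.07, 4.16 and 5.99, against 3.14 to 6.93 in HGSOC, and EnOC 5 at 0.71. Both differences thus rest largely on CCOC and MOC in the mean of the others.

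Serous markers had a median of 1.507 in HGSOC with 2 of 20 higher, and 4 when adjusted over the list alone (camera adjusted p = 6.18e-08, adjusted p = 0.213 with an estimated correlation). The mean level of these markers was 1.68 log2 CPM in HGSOC 4 and at least 5.58 in the other HGSOC tumours. The WT1 call was lost without CCOC 2, 3 or 4, EnOC 1, 2 or 5, HGSOC 1, 2 or 5, or MOC 1, 3 or 4, with an adjusted p of up to 0.162 without HGSOC 1. Gastrointestinal mucinous genes had a median of −4.389 with 0 of 27 called, and 18 lower when adjusted over the list alone (camera adjusted p = 4.36e-12, adjusted p = 0.0916 with an estimated correlation). Their mean level was −1.578 to −0.509 log2 CPM in HGSOC, −1.069 to 0.826 in CCOC and −1.508 to 2.192 in EnOC. In MOC it was 1.67 to 5.925, so this difference rests largely on MOC in the mean of the others. Clear cell markers had a median of −1.843 with 0 of 17 called, and 10 lower when adjusted over the list alone (camera adjusted p = 2.52e-08, adjusted p = 0.0916 with an estimated correlation). The mean level of clear cell markers was 2.56 to 3.46 log2 CPM in HGSOC and 2.76 to 5.08 in EnOC. It was 3.48 to 4.63 in MOC and 3.85 to 7.94 in CCOC.

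Interferon response genes had a median of 1.309 with 0 of 19 called, and 2 higher when adjusted over the list alone (camera adjusted p = 1.68e-09, adjusted p = 0.247 with an estimated correlation). MHC class II genes had a median of 1.545 with 0 of 11 called, and 7 higher when adjusted over the list alone (camera adjusted p = 3.81e-08, adjusted p = 0.23 with an estimated correlation). Among lists of other cell types, T and NK cell genes had a median of 0.52 with 0 of 21 called, and 0 when adjusted over the list alone (camera adjusted p = 0.0123, adjusted p = 0.609 with an estimated correlation), and lost the call without EnOC 4 (0.0562) or HGSOC 4 (0.183). Fibroblast genes had a median of 0.561 with 0 of 20 called, and 0 when adjusted over the list alone (camera adjusted p = 0.0479, adjusted p = 0.812 with an estimated correlation). Their call was lost without CCOC 2 or 3, EnOC 4 or 5, HGSOC 2, 4 or 5, or MOC 1, 2, 3 or 4, with a median of −0.011 without HGSOC 2 (camera adjusted p = 0.875). Hypoxia genes had a median of −0.941 with 0 of 22 called, and 4 lower when adjusted over the list alone (camera adjusted p = 7.48e-06, adjusted p = 0.153 with an estimated correlation). Mesothelial genes had a median of 1.411 with 1 of 11 higher, and 5 when adjusted over the list alone (camera adjusted p = 0.000472, adjusted p = 0.0916 with an estimated correlation). Epithelial genes had a median of −0.572 with 0 of 20 called, and 0 when adjusted over the list alone (camera adjusted p = 0.00031, adjusted p = 0.609 with an estimated correlation). Their call ended without HGSOC 4 (median −0.282, camera adjusted p = 0.748), the tumour in which they averaged 0.93 log2 CPM against at least 6.14 in the other HGSOC tumours.

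In HGSOC, 61 genes passed in edgeR, 51 higher and 10 lower, and this count moved with many single libraries. It was 20, 15 and 27 without CCOC 2, 3 and 4, 23, 5 and 11 without EnOC 1, 2 and 5, 11, 27, 100 and 14 without HGSOC 1, 2, 4 and 5, and 31, 14 and 19 without MOC 1, 3 and 4. DESeq2 called 991 genes, 408 higher and 583 lower, and edgeR called 3 with the other tumours pooled as 1 group and 120 without the 5 doubted libraries.

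Mucinous tumours differed in genes of the stomach and intestine. TFF2 (ENSG00000160181), a gastric trefoil peptide, was higher by 12.84 ± 1.29 (adjusted p = 4.69e-05), at 6.22 ± 5.41 log2 CPM in MOC and −2.32 ± 1.14 in the others (SD, n = 5 and 14). TFF3 was higher by 8.47 ± 0.97 (adjusted p = 0.000129), at 6.75 ± 2.25 and −0.42 ± 2.3 log2 CPM. OLFM4, a marker of intestinal stem cells, was higher by 9.72 ± 1.08 and REG4, a secreted lectin of the gut, by 9.75 ± 1.19 (adjusted p = 0.000129 and 0.000203). SLC6A12, a betaine transporter, was lower at −4.04 ± 0.76 (adjusted p = 0.00891).

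Of the 27 gastrointestinal mucinous genes measured, 20 rose in MOC and 7 did not pass, and 27 rose when adjusted over the list alone. Their median was 6.23 (camera adjusted p = 3.23e-43, and 0.000315 with an estimated correlation). The mean level of these genes was 1.67 log2 CPM in MOC 2 and 4.654 to 5.925 in the other MOC tumours. It was 2.192 in EnOC 5, so MOC 2 did not share this programme to the same degree. LGALS4, an intestinal galectin, was higher by 6.86 ± 1.09 (adjusted p = 0.0024), though at −0.88 log2 CPM in MOC 2. CDX2, an intestinal transcription factor, was at 5.37 and did not pass (adjusted p = 0.0891), with −3.7 log2 CPM, the level of 0 counts, in MOC 2 and MOC 4. Serous markers had a median of −1.691 with 0 of 20 called, and 8 lower when adjusted over the list alone (camera adjusted p = 1.87e-07, adjusted p = 0.306 with an estimated correlation). Glucose and glycogen genes had a median of 0.616 with 2 of 14 higher, and 3 when adjusted over the list alone (camera adjusted p = 0.00592, adjusted p = 0.203 with an estimated correlation). Among them FBP1, which encodes a gluconeogenic phosphatase, was higher by 2.26 ± 0.45 (adjusted p = 0.0141), with the call lost without MOC 3 or MOC 4 (up to 0.0837). Ovarian stromal and steroidogenic genes had a median of 0.816 with 2 of 15 higher, and 2 when adjusted over the list alone (camera adjusted p = 0.0069, adjusted p = 0.889 with an estimated correlation), and −0.154 without MOC 5 (camera adjusted p = 0.411).

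In MOC, 325 genes passed in edgeR, 314 higher and 11 lower. The count was 199 without MOC 3, 141 without MOC 4, and 205, 196 and 199 without EnOC 1, 2 and 4, and 651 without the 5 doubted libraries. DESeq2 called 841 genes and limma-voom 185. No gene passed against all 3 other histotypes at once in any of the 4 histotypes (0 in edgeR), which the 0 genes in each pair with EnOC fix in advance, beside 5123, 1819, 3752 and 3285 genes at an unadjusted p under 0.05 against the mean of the others in CCOC, EnOC, HGSOC and MOC. With no difference, a share of about 0.05 of the 29170 genes would reach such an unadjusted p. DESeq2 was not run for each other histotype separately. Single tumours carried part of the list. TFF1 was at 9.78 ± 1.73 and at 6.19 without MOC 4 (adjusted p = 0.0541), LYZ, lysozyme, at 8.7 ± 1.26 and at 2.95 without MOC 4 (0.0508), and DMBT1 at 8.46 ± 1.37 and at 4.46 without MOC 3 (0.0632).

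**Figure D3:**
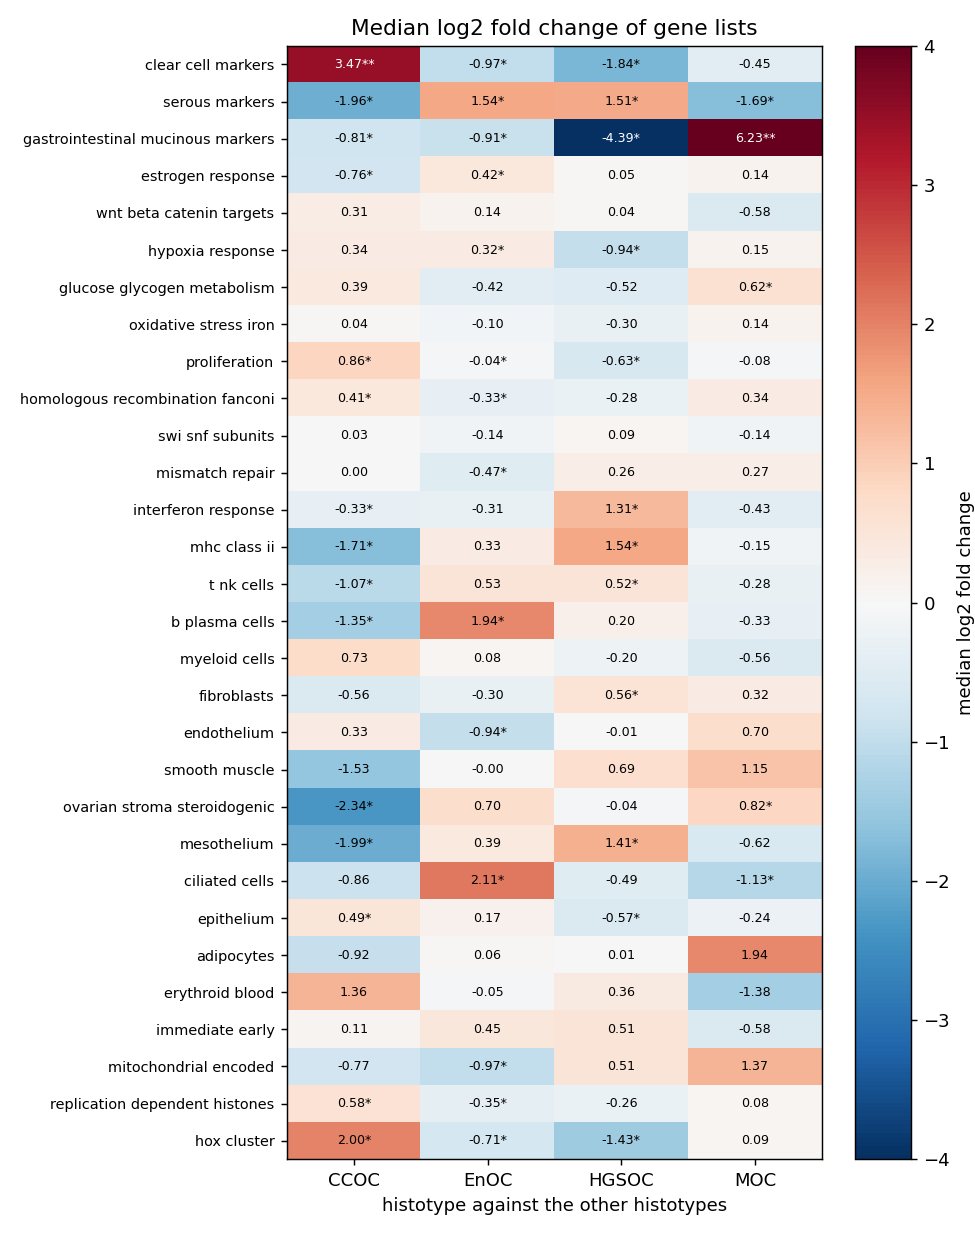
Median log2 fold change of the 30 gene lists (one line each) in each histotype against the mean of the others, on a colour scale that ends at 4 either way. One star marks a camera adjusted p under 0.05 and 2 stars mark lists that also passed with an estimated correlation, which were the clear cell markers in CCOC (median 3.474) and the gastrointestinal mucinous genes in MOC (median 6.23).

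Pairs of histotypes were also compared directly. CCOC and HGSOC differed in 475 genes, CCOC and MOC in 91, and HGSOC and MOC in 30 (edgeR). The 3 pairs with EnOC gave 0 genes each in edgeR, beside 3339 for CCOC, 1514 for HGSOC and 2240 for MOC at an unadjusted p under 0.05. A share of about 0.05 of the 29170 genes would do so with no difference, and the 1514 for HGSOC was near that level. The mean Spearman correlation of EnOC with HGSOC tumours was 0.841, against 0.832 among EnOC tumours.

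The last question was whether genes close to histotype-restricted H3K27ac regions were more highly transcribed in that histotype. Genes whose start lay nearest to a CCOC-restricted region, within 50 kb, had a median log2 fold change of 0.739 in CCOC (373 genes, 86.1% positive, camera p = 2.52e-28, and 3.92e-05 with an estimated correlation). Of these, 82 were called higher and 1 lower. If the 16631 protein-coding genes were independent and equally likely to be called, 12.3 higher genes would be shared (odds ratio 9.5, Fisher's exact p = 2.13e-44). This p takes genes as samples and does not measure the spread between tumours. The genes called higher included DPPA2, HAVCR1, a kidney injury marker, at 6.46, GPX3, a secreted glutathione peroxidase, at 5.13, and SPP1, osteopontin, at 3.65. The 88 genes near MOC-restricted regions had a median of 0.551 in MOC (camera p = 7.39e-18, and 3.99e-05 with an estimated correlation), with 10 called higher, among them ADH1C at 7.81 ± 1.07 and TMPRSS2, a serine protease, at 3.73 ± 0.81. The 149 genes near HGSOC-restricted regions had a median of 0.419 in HGSOC (camera p = 3.71e-07, and 0.0146 with an estimated correlation), with DAPL1 at 6.18 ± 0.86, CYP1B1 at 3.19 ± 0.66 and TPRG1 at 2.53 ± 0.51 called higher. The 20 genes near EnOC-restricted regions had a median of 0.213 (camera p = 0.0276, and 0.17 with an estimated correlation). The EnOC call was lost without EnOC 1, EnOC 2, EnOC 4 or MOC 3, where the medians were 0.104, 0.283, 0.001 and 0.149 and camera gave p-values of 0.289, 0.0984, 0.302 and 0.0699. Within 10 kb the EnOC median was −0.025. The HGSOC median was 0 for regions within 1 kb of the start.

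**Figure D4:**
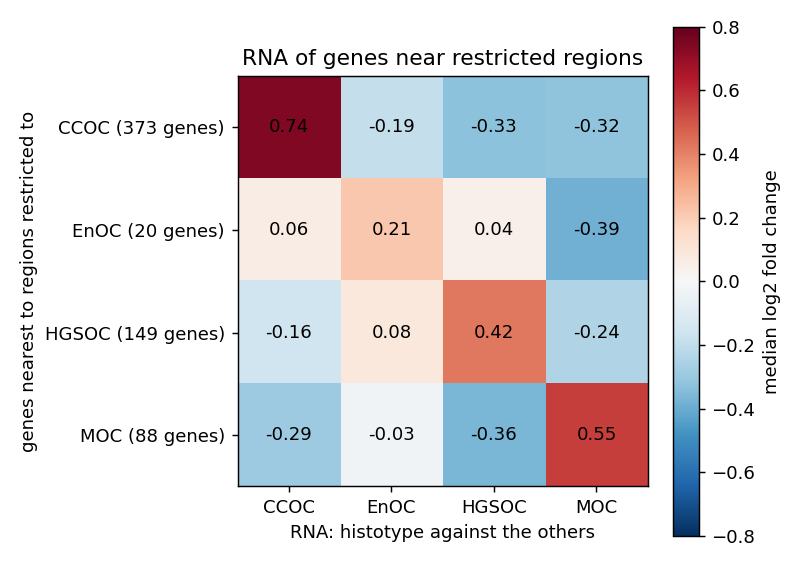
Median log2 fold change, as colour and number, of the genes nearest to regions restricted to each histotype (one axis) in each RNA comparison of a histotype with the mean of the others (other axis). Values for the matching histotype were 0.739 in CCOC, 0.213 in EnOC, 0.419 in HGSOC and 0.551 in MOC.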

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

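The tests of other splits of the tumours, the albumin comparison and the ranges set beside the EnOC spread were chosen only after the result was seen. The list of adult liver genes was written after the abundance of APOA1 had been seen.

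A tumour was singled out where its gap to the nearest other tumour of its histotype was large against the range of that histotype. This held in 12 of 109 groups of values, where chance alone gives about 1 in 20. In CCOC 1, AFP was at 10.05 log2 CPM (nearest −1.04) and the mean of B and plasma cell genes at −0.14 (nearest −1.53). In CCOC 5, DMBT1 was at −1.87 and MGAM2 at −2.51, where the other 4 CCOC tumours were at −3.7, the level of 0 counts, for both. With 4 tumours at 0 any count in the fifth is singled out, so these 2 show nothing beyond a few counts. EnOC 2 had 121903 peaks (nearest 72654) and a mean of 2.08 for homologous recombination genes (nearest 3.16). EnOC 5 had 40.71% of counts in mitochondrial ribosomal RNA (nearest 12.33). EnOC 1 had ENPP3 at −2.94 (nearest 4.09). HGSOC 4 had serous markers at a mean of 1.68 (nearest 5.58), epithelial genes at 0.93 (nearest 6.14) and FXYD1 at 5.66 (nearest 2.44). MOC 1 had TFF3 at 10.71 (nearest 6.33).

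No gene passed in EnOC RNA, and 3 technical explanations were weighed. A group of 4 rather than 5 tumours may contribute: with 1 own tumour left out, the 15 counts of CCOC, HGSOC and MOC ran from 11 to 986, 13 of them at 20 or more and 0 at 5 or fewer, which missed the bound set beforehand (all 15 at 20 or more), while simulated 16-fold changes were recovered at 93% with 4 EnOC tumours. Other splits gave a median of 10 genes for groups of 4 placed as EnOC. The medians for groups of 5 placed as CCOC, HGSOC and MOC were 1, 0 and 0, so a group of 4 did not by itself hold the count at 0. These splits do not measure the power to find genes of EnOC. The simulation gave every EnOC tumour the same fold, so it cannot settle this either. The mitochondrial-rich library EnOC 5 is argued against as the main cause. Without it 5 genes passed, exactly on the bound set beforehand against this explanation (5 or fewer), beside 2 without EnOC 1, 6 without EnOC 2 and 34 without EnOC 4. EnOC stayed at 0 genes with all mitochondrial-rich libraries left out, and at 0 without the 5 doubted libraries. For a wider spread among EnOC tumours, the median SD of log2 CPM was 0.94, against 0.99 in CCOC, 0.92 in HGSOC and 0.99 in MOC. Being below CCOC and MOC met the bound set beforehand against this explanation. At the same group size it lay inside the ranges of 4 tumours in CCOC (0.86 to 1.02), HGSOC (0.84 to 0.95) and MOC (0.82 to 1), so it was neither clearly wider nor narrower. None of the 3 was shown to be the cause, and their partial contributions cannot be told apart here. That endometrioid tumours lack transcripts of their own stays open as an untested biological explanation.

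Some liver-type genes were high in CCOC 1, where APOA1 was at 6530 CPM, APOA2 at 1380 and AFP at 10.05 log2 CPM. Other such genes were not, as UGT1A9 and LBP were at −1.682 log2 CPM in CCOC 1 and at 8.112 and 6.931 in CCOC 3. Adult liver cells that brought all their abundant transcripts are argued against by albumin, as ALB was at 3.81 CPM and 9 of the 14 liver genes were under 1% of APOA1. By the bounds set beforehand the count of liver genes over 10 CPM, 8 of 14, was undecided between liver tissue in the core and none, so other liver-like cells may still be a source. A wrong label was not tested, nor was any biological explanation.

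Other splits of the tumours into groups of the same sizes, 100 in all for each result, were counted. In RNA, 1 of 100 splits, the histotypes themselves, was as large for CCOC (910 genes, highest other split 705) and for MOC (325, highest other 214). This is the smallest share that 100 splits can give, and it is not adjusted over the 4 histotypes. It argues against chance for CCOC and MOC but does not exclude it. Chance stays open for HGSOC (61, highest other 257, 9 of 100), and in EnOC all 100 splits gave at least the observed 0 (highest other 429). The highest other split for each histotype (705, 429, 257 and 214 genes) put CCOC 1 and HGSOC 4 into the same group, with at most 2 tumours of any histotype in it, which points to a structure of the samples other than histotype. The next highest (129, 240, 240 and 179 genes) held 3 or 4 tumours of CCOC or MOC, so histotype itself enters some splits. For the adjusted H3K27ac test all 100 splits gave at least the observed 0 in each histotype (highest other 0), which tests nothing. For restricted regions, 3 of 100 splits were as large for CCOC (663) and 3 of 100 for HGSOC (357). These shares are not adjusted over the 4 histotypes, so they argue against chance but do not exclude it. Chance stays open for EnOC (32, 50 of 100) and MOC (146, 9 of 100). The highest other split held 811 regions in each case and put all 3 of the longest peak lists into 1 group, and fell to 54 with the same number of strongest peaks from each tumour, which points to long lists or their weaker peaks for that split. The next held 668 regions, with 0 of the 3 longest lists and 3 tumours of 1 histotype in the group, and 523 at the same number of peaks, so list length does not account for it. At the same number of peaks, 2 of 100 splits were as large for CCOC (302), 2 for HGSOC (277), 4 for MOC (167) and 30 for EnOC (33), with 523 as the highest other. For MOC, the step from 9 to 4 of 100 is too small to be tied to list length.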

How the results depend on the processing

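Leaving out the mitochondrial-rich or the 5 doubted libraries, asking for 3 of 4 own tumours, the depleted regions, the centres of regions and testing gene lists under DESeq2 size factors or the stricter filter were chosen only after the result was seen. The cause was not tested for any change below unless stated. Fewer counts limit low genes most, as the smallest library held 7416560 counts, and the number of tumours limits the tests of single regions.

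Called genes in CCOC, HGSOC and MOC numbered 2090, 991 and 841 with DESeq2, 355 (CCOC) and 185 (MOC) with limma-voom, and 592, 39 and 128 with a stricter filter, which tests fewer genes. The EnOC count was 42 with DESeq2, 1 with limma-voom, 109 with no filter and 18 with no scaling beyond library size. HGSOC gave 152 genes with no filter, and no scaling gave 522 in CCOC and 16 in HGSOC. With the others as 1 group, HGSOC gave 3 and MOC 170. Against all 3 other histotypes at once, CCOC, HGSOC and MOC gave 0 (edgeR), fixed by the 0 genes in the pairs with EnOC. Without the 5 doubted libraries HGSOC gave 120 and MOC 651. DESeq2 called 1121 genes higher and 969 lower in CCOC, and 408 and 583 in HGSOC, where edgeR called 753 and 157, and 51 and 10. With each tumour left out in turn the counts ran from 408 to 986 in CCOC, 0 to 34 in EnOC, 5 to 100 in HGSOC and 141 to 395 in MOC.

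The tumour numbers do not pair the tumours: over 27 same-number pairs the correlations of deviations ran from −0.257 to 0.234, with 8 over 0.1. With the replicate number as a block, the counts were 241 in CCOC, 1 in HGSOC and 84 in MOC and the EnOC count stayed at 0 (edgeR). The genes near EnOC-restricted regions then lost the call, with a median of 0.178. The block moved no count of gene lists by over 1.5 times, and the adjusted region test stayed at 0, as it did without it. Restricted and depleted regions were not run with the block.

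Gene lists past the test numbered 1, 0, 0 and 1 with an estimated correlation and 3, 1, 3 and 1 with fry in CCOC, EnOC, HGSOC and MOC. In MOC, 8 lists passed with no filter, 8 without the doubted libraries and 3 with a stricter filter. With each tumour left out, 8 to 16 lists passed in CCOC (8 without CCOC 2), 10 to 16 in EnOC, 10 to 17 in HGSOC and 4 to 10 in MOC (8 without EnOC 5 and 10 without MOC 1). Proliferation genes in EnOC turned to 0.317 without EnOC 2 (−0.495 to 0.317 over all tumours left out), and myeloid genes in EnOC to −0.46 without EnOC 1 (−0.46 to 0.362). AFP in CCOC turned to −0.83 without CCOC 1 (−0.83 to 9.7 over all) and −0.01 without the doubted libraries, CD7 in CCOC to −1.38 (−1.38 to 3.75) and −1.39, and CCL5 in CCOC to −1.27 without CCOC 3 (−1.27 to 4.62). Of other values, 6487 for named genes and 3026 for lists kept direction and side of the threshold, 602 and 203 lost the call and 128 and 121 gained it.

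Genes near EnOC-restricted regions had a median of −0.025 within 10 kb, p = 0.17 with an estimated correlation and 0.079 with fry, and 0.001 to 0.375 with each tumour left out. Genes near HGSOC-restricted regions had a median of 0 for regions within 1 kb of a start. Other medians with a tumour left out were 0.581 to 0.849 in CCOC, 0.162 to 0.468 in HGSOC and 0.408 to 0.624 in MOC.

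For H3K27ac regions the call without a test gave 663, 32, 357 and 146 regions where the adjusted test gave 0. Restricted regions in CCOC, EnOC and MOC numbered 349, 61 and 97 when at least 50% of the region had to be covered, and 1393, 86, 1162 and 483 in bins of 1 kb for CCOC, EnOC, HGSOC and MOC. With −log10 q of at least 5, EnOC had 57 restricted and 5 depleted regions and HGSOC 204 restricted. With the same number of strongest peaks per tumour, CCOC had 302 restricted and HGSOC 371 depleted regions. That setting also drops the weaker peaks, so list length and peak strength cannot be told apart. Depleted regions numbered 174, 2, 329 and 28 with 50% covered and 1236, 41, 2580 and 398 in bins. Bins split long regions, which raises counts by construction. With each tumour left out, restricted regions numbered 110 to 915, 1 to 59, 10 to 623 and 43 to 214, and depleted regions 133 to 688, 3 to 72, 412 to 1455 and 55 to 523. Without an own tumour the rule asks for all 4 left, and asking for 3 of 4 gave 1207 to 2098, 112 to 369, 450 to 2261 and 333 to 815 restricted regions. The odds ratio for promoters in shared regions ran from 31.88 to 111.35 over other windows, overlaps, centres and −log10 q. The within-histotype excess ran from 0.018 to 0.0288 (Jaccard) and 0.0183 to 0.0246 (Spearman). The difference in peak number, own minus others, ran from 9188.6 to 23233.9 in CCOC, −9859.5 to 5902.7 in EnOC, −18904.1 to −11488.3 in HGSOC and −11568 to 2110.2 in MOC.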

Other observations

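The depleted regions were defined after the peak lists had been examined. The tests of segments and of list length were chosen before their result was seen. Regions depleted in a histotype, present in at most 1 of its tumours and at least 12 others, numbered 340 in CCOC, 13 in EnOC, 848 in HGSOC and 130 in MOC, and moved by over 1.5 times with most tumours left out (133 to 688, 3 to 72, 412 to 1455 and 55 to 523). The 578 genes nearest to HGSOC-depleted regions had a median log2 fold change of −0.612 in HGSOC (camera p = 2.49e-13, and 9.24e-05 with an estimated correlation) and 0.321 in CCOC. Genes near CCOC-depleted regions had a median of −0.269 in CCOC (182 genes, camera p = 6.28e-05, and 0.0115 with an estimated correlation) and those near MOC-depleted regions −0.51 in MOC (78 genes, 2.18e-06, and 0.0173). Promoters overlapped 25.6% of the HGSOC-depleted regions, against 4.7% in CCOC, 15.4% in EnOC and 9.2% in MOC.

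Genes nearest to CCOC-restricted regions had higher RNA in CCOC, with a median of 0.74 (quartiles 0.24 and 1.71, 373 genes), and 2 technical explanations were weighed. A copy-number gain of whole segments is argued against as the whole cause, since the 4046 other genes within 500 kb had a median of 0.15 (quartiles −0.33 and 0.65), under the bound set beforehand. Longer peak lists in CCOC are argued against too, as the median was 0.96 (quartiles 0.25 and 1.95, 202 genes) with the same number of strongest peaks from each tumour. Different mixtures of cell types in the cores stay open and may account for both the mark and the RNA. That these regions act on their nearest genes is a hypothesis, found and tested on the same tumours.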
